A study of Homo sapiens with 9 samples.

How the data were processed

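MDA-MB-231 cells, a human triple-negative breast cancer line, were grown in 6-well plates and treated with DMSO, 3 nM or 30 nM YX968 for 14 h, with 3 libraries in each of the 3 groups. YX968 is a chimeric degrader (PROTAC) directed at the histone deacetylases HDAC3 and HDAC8. Poly(A) RNA libraries were sequenced as paired 150-base reads on an Illumina NovaSeq. Per the submitters' processing notes, Trimmomatic, HISAT2 and HTSeq were used with GRCh38; versions, the annotation release and the strand setting of the counting step were not given in the sources used here. Values of genes that overlap another gene, and of near-identical gene copies whose reads map to more than 1 place, are therefore uncertain.

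The deposited table from the authors holds a read count and a CPM (the count scaled to the library total) for each of 56282 genes in the 9 libraries. The deposited CPM equalled each count over its column total, with a largest difference of 3.82e-11, so counts were used and CPM was computed again after normalisation. Column totals were 37448938, 26726382 and 34392936 counts in DMSO replicates 1 to 3, 36825220, 32475713 and 16557756 at 3 nM, and 25043766, 33858876 and 37225008 at 30 nM. At these depths counting noise was a small part of the spread: the chi-square per degree of freedom within groups ran from 14.7 to 159, and the common biological coefficient of variation was 0.325.

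Genes were kept by the edgeR function filterByExpr, which left 15553 of the 25281 genes with any count. Library totals were scaled by TMM, and the 9 libraries were fitted together with 1 mean per group by the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3. The comparisons were 3 nM against DMSO, 30 nM against DMSO and 30 nM against 3 nM. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, from a 2-sided test. Levels are means of TMM-normalised CPM with SD across 3 libraries, and log2 fold changes carry a standard error (SE) from the fit. A prior count of 2 was used for log CPM. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

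Lists of genes were fixed before the data were examined, as were the comparisons and the alternative settings listed first below. There were 32 lists with 978 entries, of which 977 matched a gene in the table. They covered the enzymes and complexes of histone acetylation, cohesin (the HDAC8 substrate SMC3 belongs to it), the ubiquitin ligases used by degraders, the cell cycle, stress and metabolic pathways, cell identity, other cell types and signs of RNA quality. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset correlation of 0.01, and adjusted over the 32 lists. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone, which is a weaker correction than that over all genes.

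The rule for named genes took, in each dose against DMSO, the 10 rises and 10 falls with the largest change among genes with a symbol, an adjusted p below 0.05, a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups. For 30 nM against 3 nM it took 5 each way. Where fewer passed, each one that passed was named, and where none passed, the 5 genes with the lowest p were given as not passing. HDAC1 to HDAC11 were named whatever their values. Coordinates are GRCh38 from the GENCODE v29 annotation, 1-based.

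The relation between the doses was measured as the correlation of log2 fold changes and the overlap of calls. Both doses share the 3 DMSO libraries, which are too few to split between them. The values were therefore set beside 20 simulated data sets with no change at either dose and the same shared control.

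Alternatives set beforehand were DESeq2 1.42.0, RLE scaling, no filter, a filter of 1 CPM in 3 libraries, limma-trend with pseudocounts of 1 and 0.1, an adjusted p of 0.01, fits of only the 6 libraries compared, a block for the replicate number and each library left out in turn. Others were chosen after seeing the data: an offset that removed the trend of each library over gene GC content and length (loess span 0.5), which needed annotation and covered 14057 of the tested genes (90.4%), that offset without 30 nM replicate 3 or without 3 nM replicate 1, both replicates numbered 3 at 3 nM and 30 nM left out, and limma voom with sample weights.

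The pipeline was tested on simulated data of the same size. Among genes given a change, edgeR recovered 17.9% of 2-fold and 71.2% of 4-fold changes in 3 nM against DMSO, 29.9% and 68.2% in 30 nM against DMSO, and 28.6% and 70.2% in 30 nM against 3 nM. It made 3 false calls among 63 in 3 nM against DMSO, where DESeq2 made 32 among 119. These counts were drawn with the spread of each gene as estimated by edgeR and without GC trends of the libraries. The rates may therefore favour edgeR and need not hold for the real libraries. Figures were drawn with Python 3.11.15.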

Results

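YX968 joins a ligand of the histone deacetylases HDAC3 and HDAC8 to a recruiter of a ubiquitin ligase, and the RNA of MDA-MB-231 breast cancer cells was counted after 14 h with DMSO, 3 nM or 30 nM of it (n = 3 libraries per group). At 3 nM, 13 genes changed, 9 of them rises, 4 of which were genes of fatty acid and cholesterol handling. No gene was called at 30 nM against DMSO, and 6 genes differed between the doses. Among the 9 libraries, the trend of expression with gene GC content did not follow the groups alone. In log2 units per 10 points of GC its slope was -0.38, -0.10 and -0.27 in DMSO, -0.15, 0.19 and 0.30 at 3 nM, and 0.33, 0.30 and -0.23 at 30 nM, in the order of replicates 1 to 3.

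**Figure D1:**
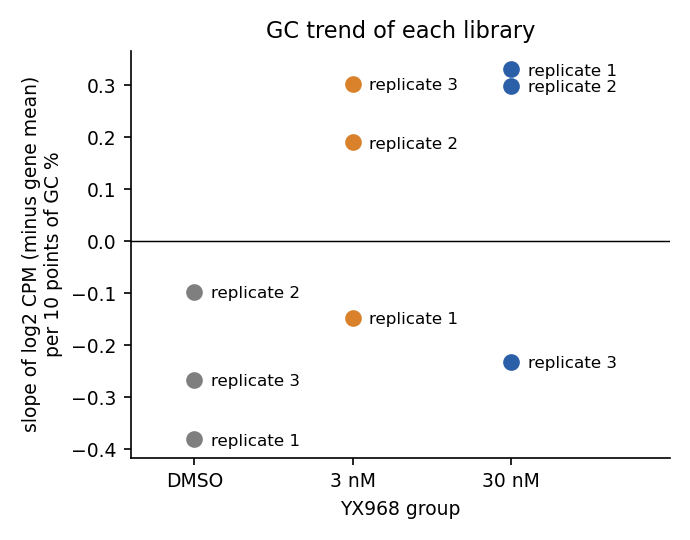
Slope of log2 CPM, relative to the mean of each gene, over gene GC content in each of the 9 libraries, by group. Values above 0 mean that GC-rich genes were relatively high in that library.

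The transcripts of both targets were present in each group, and neither passed the test. HDAC3, the catalytic subunit of the NCoR/SMRT co-repressor complexes (chromosome 5, 141620876 to 141636870), stood at 84.5 ± 3.38 CPM in DMSO, 105 ± 17.8 CPM at 3 nM and 96.6 ± 6.87 CPM at 30 nM. Its log2 fold changes were 0.31 (SE 0.15, adjusted p = 0.324, edgeR) and 0.19 (SE 0.15, adjusted p = 0.522). HDAC8, which deacetylates the cohesin subunit SMC3 (X chromosome, 72329516 to 72573199), stood at 22.9 ± 2.07, 20.7 ± 2.26 and 21.5 ± 2.55 CPM, with log2 fold changes of -0.15 (SE 0.18, adjusted p = 0.669) and -0.09 (SE 0.18, adjusted p = 0.823). With the GC and length offset the HDAC8 values turned to 0.26 and 0.29. HDAC3 overlaps a gene on the other strand, and protein was not measured.

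The other members of the classical deacetylase family did not pass either without the offset, with adjusted p from 0.129 to 0.919 at 3 nM and from 0.403 to 0.964 at 30 nM over HDAC1 to HDAC11 (edgeR). At 3 nM and 30 nM the log2 fold changes were 0.10 and 0.12 for HDAC1, -0.46 and -0.46 for HDAC2, 0.33 and 0.27 for HDAC4, 0.55 and 0.58 for HDAC6, 0.44 and 0.34 for HDAC7, 0.17 and -0.10 for HDAC10, and -0.15 and 0.44 for HDAC11. HDAC5, a class IIa enzyme, had 48.2 ± 7.23 CPM in DMSO, 118 ± 32.9 CPM at 3 nM and 67.4 ± 18.5 CPM at 30 nM, at 3 nM a log2 fold change of 1.29 (SE 0.25, adjusted p = 0.129; 0.00491 when adjusted over the list alone). With the offset HDAC5 passed (log2 0.96, adjusted p = 0.0259), 1 of 5 alternatives among 16 in which it passed, with adjusted p from 4.17e-05 to 0.732 over the 16. HDAC9 had -0.69 (adjusted p = 0.223; 0.0276 over the list alone), which the offset moved to -0.15. The offset turned HDAC2 to 0.11 and 0.05, HDAC10 at 3 nM to -0.14 and HDAC9 at 30 nM to 0.16. HDAC2, HDAC4, HDAC5, HDAC7, HDAC9 and HDAC11 overlap genes on the other strand, and HDAC4, HDAC7, HDAC8 and HDAC10 overlap genes on the same strand. Over the list alone, 1 of the 18 deacetylases and sirtuins was higher and 1 lower at 3 nM, and the list as a whole had an adjusted p of 0.290 at 3 nM and 0.334 at 30 nM (camera).

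At 3 nM, 4 genes of fatty acid and cholesterol handling rose. SCD, the desaturase that makes monounsaturated fatty acids (chromosome 10, 100347124 to 100364834), went from 158 ± 2.90 CPM in DMSO to 471 ± 65.5 CPM, a log2 fold change of 1.58 (SE 0.14, n = 3 per group, adjusted p = 0.00215, edgeR). ABCA1, the exporter of cellular cholesterol and a target of the nuclear receptor LXR (chromosome 9, 104781002 to 104928237), rose 4.11-fold from 7.04 ± 1.00 CPM in DMSO (log2 2.04, SE 0.23, adjusted p = 0.00758). SREBF1, which encodes the regulator of fatty acid synthesis SREBP1 (chromosome 17, 17810399 to 17837002), rose 3.50-fold (log2 1.81, SE 0.24, adjusted p = 0.0169). ANGPTL4, a secreted inhibitor of lipoprotein lipase (chromosome 19, 8363289 to 8374373), rose 2.49-fold from 78.8 ± 3.55 to 196 ± 40.6 CPM (log2 1.32, SE 0.17, adjusted p = 0.0169).

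Another 5 genes rose at 3 nM. SCNN1A, the alpha subunit of the epithelial sodium channel (chromosome 12, 6346843 to 6377730), had the largest change, from 0.566 ± 0.288 to 6.20 ± 0.638 CPM (log2 3.46, SE 0.51, adjusted p = 0.0316, edgeR). GGT1, a gamma-glutamyltransferase of glutathione breakdown, rose 4.18-fold (log2 2.06, SE 0.27, adjusted p = 0.0169). S100A2, a calcium-binding protein of basal epithelia (chromosome 1, 153561108 to 153567890), rose from 22.7 ± 5.76 to 93.6 ± 18.9 CPM (log2 2.05, SE 0.24, adjusted p = 0.00758). LTBP3, which binds latent TGF-beta in the matrix (chromosome 11, 65538805 to 65558930), rose from 17.5 ± 2.70 to 66.5 ± 1.01 CPM (log2 1.93, SE 0.26, adjusted p = 0.0179). NR1D1, the circadian repressor REV-ERB alpha, which acts through NCoR and HDAC3, rose 3.43-fold (log2 1.78, SE 0.26, adjusted p = 0.0316). SCNN1A, GGT1, ABCA1, SREBF1, NR1D1 and ANGPTL4 overlap annotated genes on the other strand. GGT1 and SREBF1 also overlap genes on the same strand, and GGT1 has close copies. The levels of these genes are less certain.

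The 4 falls at 3 nM were of secreted and metabolic genes. ANOS1, an extracellular matrix protein (X chromosome, 8528874 to 8732186), fell from 37.5 ± 2.47 to 13.3 ± 0.460 CPM (log2 -1.49, SE 0.18, adjusted p = 0.00758, edgeR). CXCL1, a neutrophil chemokine driven by NF-kB (chromosome 4, 73869393 to 73871242), fell from 155 ± 9.44 to 70.7 ± 5.08 CPM (log2 -1.13, SE 0.13, adjusted p = 0.00758). AOX1, an aldehyde oxidase (chromosome 2, 200585868 to 200677064), and IGFBP3, a carrier of insulin-like growth factors (chromosome 7, 45912245 to 45921874), fell by 0.87 (SE 0.13, adjusted p = 0.0379) and 0.85 (SE 0.13, adjusted p = 0.0379) on the log2 scale. In each of the 13 genes, the 3 libraries at 3 nM lay beyond the 3 of DMSO.

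**Figure D2:**
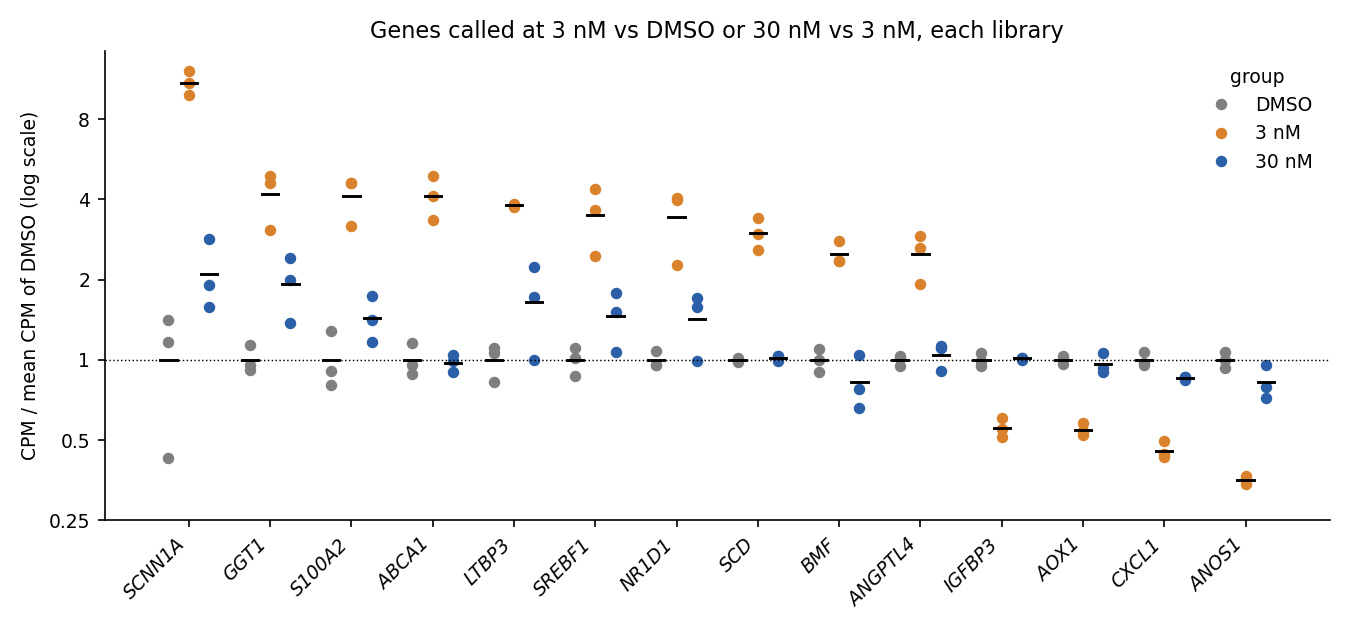
CPM of each library over the mean of DMSO, on a log axis, for the 13 genes called at 3 nM against DMSO and for BMF, called at 30 nM against 3 nM. Each point is a library and black bars are group means.

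Of 15553 genes, 2508 had an unadjusted p below 0.05 at 3 nM, where chance gives 778, and with the offset 2308 of 14057. The libraries of the groups did not overlap in 24.6% of genes, where chance gives 10%. Here and below these chance values are means. Genes that share the GC trend of a library vary together, so a count without any effect of the dose can lie far from them. DESeq2 called 354 genes, and edgeR with the GC and length offset called 64, the 13 among them. With the offset the log2 fold change was larger for ABCA1 (2.37) and SCD (1.70). It was smaller for the others of the 13, such as SREBF1 (1.44) and ANOS1 (-1.01). Calls fell to 1, 2 and 0 without DMSO replicate 1, 2 or 3 and to 1 and 2 without 3 nM replicate 2 or 3, and they came to 43 without 3 nM replicate 1 and 127 without 30 nM replicate 3. All 13 genes kept their direction in 16 alternatives, while the number of these in which they passed ran from 5 for IGFBP3 to 15 for SCD. The kept direction says little, since leaving out a library could hardly turn a sign in genes without overlap between the groups.

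Of the 32 gene lists, 10 were called at 3 nM by camera, and none of the 10 held with an estimated correlation. The list of fatty acid, PPAR and LXR target genes was higher, with a median log2 fold change of 0.26 (26 members tested, adjusted p = 1.75e-08; adjusted p = 0.167 with an estimated correlation; fry 0.0147). SCD, ABCA1, ANGPTL4 and SREBF1 rose, and 22 members did not pass. Adjusted over the list alone, 8 passed, adding the lipid droplet coat gene PLIN2 at 0.90 (adjusted p over all genes = 0.129), the fatty acid synthase gene FASN at 1.27 (0.167), the LXR alpha gene NR1H3 at 0.82 (0.217) and the acetyl-CoA carboxylase gene ACACA at 0.45 (0.243). Cholesterol synthesis genes had a median of 0.27 (25 tested, adjusted p = 0.0164; 0.316 with an estimated correlation), and DHCR7, the last enzyme of the pathway, passed over the list alone at 1.25.

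**Figure D3:**
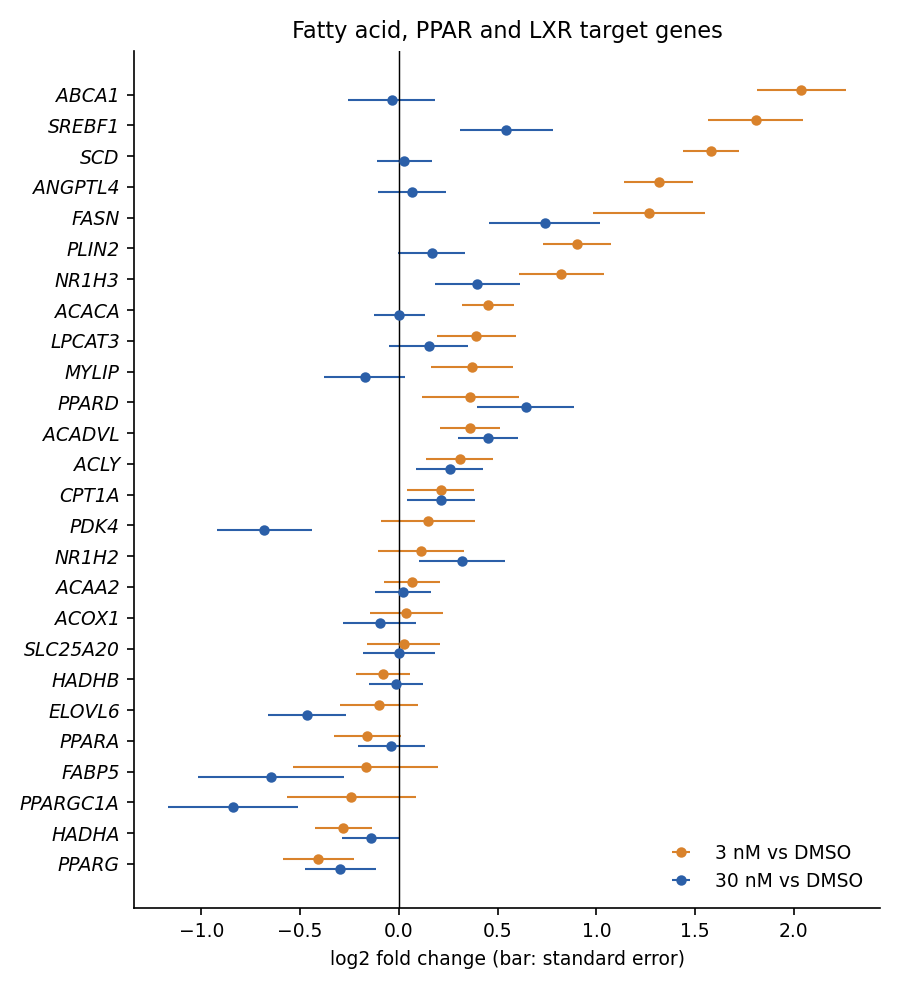
Log2 fold change with its standard error for the 26 tested genes of the fatty acid, PPAR and LXR list at 3 nM and 30 nM against DMSO. At 3 nM ABCA1, SREBF1, SCD and ANGPTL4 passed the test over all genes, and at 30 nM no gene did.

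Immediate early, MYC and ribosome, and hypoxia and glycolysis lists were also called higher at 3 nM, although no member passed over all genes. Immediate early genes had a median log2 fold change of 0.44 (31 tested, camera adjusted p = 3.70e-04; 0.316 with an estimated correlation), and over the list alone 8 passed, among them the phosphatase gene DUSP5 at 0.80, the nuclear receptor NR4A1 at 1.62 and MYC at 0.45. Genes of MYC and ribosome biogenesis had a median of 0.23 (32 tested, adjusted p = 0.0164; 0.316 with an estimated correlation; 0.111 without 3 nM replicate 1), with 0 passing over the list alone. Ribosomal protein genes, fixed as a sign of RNA quality, had a median of 0.37 (59 tested, adjusted p = 1.10e-10; 0.316 with an estimated correlation); they have many near-identical copies. Hypoxia and glycolysis genes had a median of 0.26 (34 tested, adjusted p = 0.00207; 0.316 with an estimated correlation), and over the list alone 4 passed: DDIT4, an inhibitor of mTORC1, at 1.33, VEGFA at 0.69, ENO2 at 0.63 and GAPDH at 0.87.

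Of the cell identity lists, the mesenchymal and the epithelial were called higher at 3 nM and the neuronal was not. Mesenchymal genes had a median log2 fold change of 0.39 (32 tested, camera adjusted p = 0.00637; 0.292 with an estimated correlation), and over the list alone 8 were higher, among them integrin alpha 5 (ITGA5) at 0.82 and vimentin (VIM) at 0.80, while the transcription factors SNAI2 and ZEB1 were lower at -0.68 and -0.48. With the offset SNAI2 and ZEB1 had -0.22 and 0.05 and no longer passed over the list alone (0.438 and 0.901). SPARC (57.5 CPM) and CDH2 (23.9 CPM), both in that 8, came from 3 nM replicate 1, where no other library held above 1.36 and 2.69 CPM. Without that library the list had an adjusted p of 0.0315. Epithelial and luminal genes had a median of 0.30 (24 tested, adjusted p = 0.0376; 0.316 with an estimated correlation), lost without DMSO replicate 2 (0.0516), without 3 nM replicate 2 (0.0505) and with the offset (0.0798), where the median stayed at 0.30. The keratins KRT7, KRT8 and KRT18 and the claudin CLDN7 passed over the list alone, at 0.87, 0.85, 0.79 and 0.90.

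Stress and interferon genes gave the remaining calls at 3 nM. The list of NRF2, heat shock and metallothionein genes had a median log2 fold change of 0.19 (26 tested, camera adjusted p = 0.0376; 0.316 with an estimated correlation), lost without 3 nM replicate 1 (0.111) and with the offset (0.0590), where the median was 0.22. Over the list alone 4 were higher, the heme oxygenase gene HMOX1 at 1.46, HSPA1A at 1.83, HSPA1B at 0.77 and MT1E at 1.11, and 2 were lower, the cystine transporter SLC7A11 at -1.11 and HSPH1 at -0.81. HSPA1A and HSPA1B are near-identical copies. Interferon-stimulated genes were lower, with a median of -0.26 (39 tested, adjusted p = 0.0450; 0.524 with an estimated correlation) and 0 passing over the list alone, and this was lost without DMSO replicate 2 (0.0516), 3 nM replicate 1 (0.111) or 3 nM replicate 3 (0.0715). With the offset the median was -0.03 (adjusted p = 0.0219; 0.691 with an estimated correlation). The 22 lists not called had adjusted p from 0.0601 to 0.983.

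Some members of lists that were not called passed at 3 nM, most of them only over the list alone. In the NF-kB and inflammatory list (camera adjusted p = 0.848 at 3 nM, 0.621 at 30 nM) CXCL1 fell, and over the list alone the chemokine CXCL8 at -1.13, the ubiquitin editor TNFAIP3 at -0.75 and BIRC3 at -1.21 were lower, while the urokinase gene PLAU at 0.82 and TNFAIP2 at 1.20 were higher. Of the genes commonly induced by HDAC inhibitors (0.0641, 0.342), SCNN1A rose, and over the list alone 3 were higher and 0 lower. With the offset 5 were higher and 3 lower over the list alone. Over all genes 2 were then higher and 1 lower, the latter CDKN1A (log2 -0.72, adjusted p = 0.0417, edgeR). Among apoptosis regulators (0.907, 0.493), BMF and BBC3, both pro-death BH3-only genes, passed over the list alone at 1.32 and 1.49.

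At 30 nM no gene was called against DMSO by edgeR, where the lowest adjusted p was 0.403. The 5 genes with the lowest p, none passing, were each higher: LENG8 at a log2 fold change of 1.12 (SE 0.20, adjusted p = 0.403; 83.3 ± 6.56 to 181 ± 58.4 CPM), MROH6 at 1.35 (SE 0.25, 0.403), the GTP-binding protein gene GTPBP2 at 0.77 (SE 0.17, 0.403), the oxysterol-binding protein relative OSBPL7 at 1.26 (SE 0.27, 0.403) and PIDD1, a p53-induced death domain protein, at 0.99 (SE 0.22, 0.403). The GC content of these 5 genes ran from 55.0% to 68.4%. With the offset they had 0.68, 0.81, 0.54, 0.85 and 0.48 in the same order (adjusted p = 0.775 each, edgeR). LENG8 had 248 CPM in 30 nM replicate 1 and 147 CPM in replicates 2 and 3. LENG8, GTPBP2 and PIDD1 overlap genes on the other strand. The genes called at 3 nM had values nearer 0 here: SCD 0.03, ABCA1 -0.04, ANGPTL4 0.06, SREBF1 0.54, SCNN1A 1.08, GGT1 0.94, S100A2 0.52, LTBP3 0.72, NR1D1 0.51, ANOS1 -0.28, CXCL1 -0.23, AOX1 -0.05 and IGFBP3 0.02. In the same order the offset gave 0.10, 0.20, -0.34, 0.07, 0.77, 0.51, 0.39, 0.13, 0.13, 0.14, -0.03, 0.08 and 0.01.

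An unadjusted p below 0.05 was found at 30 nM for 1771 genes, 1047 higher and 724 lower, where chance gives 778, and with the offset for 886 of 14057 genes, and groups did not overlap in 14.6% of genes, where chance gives 10%. DESeq2 called 14 genes, each higher, limma-trend and the offset fit called 0, and edgeR without 30 nM replicate 3 called 2856. In that last fit the mean GC content was 59.1% for genes called higher and 39.8% for genes called lower, against 49.4% for the genes tested, and with the offset as well it called 0, with 1947 genes at an unadjusted p below 0.05.

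Cell division genes were lower at 30 nM as lists, with no member passing. Genes of G2 and mitosis had a median log2 fold change of -0.25 (54 tested, camera adjusted p = 4.53e-04, or 0.805 with an estimated correlation). With the offset the median was -0.10 (camera adjusted p = 8.63e-04, or 0.766 with an estimated correlation). S phase genes had a median of -0.27 (43 tested, adjusted p = 0.00648; 0.805 with an estimated correlation), and -0.07 with the offset (0.0452; 0.766 with an estimated correlation). The S phase call with the offset was lost when 3 nM replicate 1 was left out as well (0.0544, camera). Cohesin genes had a median of -0.48 (16 tested, camera adjusted p = 0.0133, or 0.805 with an estimated correlation). With the offset the median was -0.11 and the call was lost (camera adjusted p = 0.101). Ribosomal protein genes had a median of 0.24 (59 tested, adjusted p = 0.0177; 0.807 with an estimated correlation), lost without DMSO replicate 1 (0.191), DMSO replicate 3 (0.230) or 30 nM replicate 2 (0.237). In these 4 lists 0 members passed over the list alone, and the other 28 lists had adjusted p from 0.124 to 0.954. At 3 nM the lists of G2 and mitosis (0.0612), S phase (0.308) and cohesin (0.309) were not called, and at 30 nM against 3 nM they had 0.0772, 0.0517 and 0.0772 (0.0217, 0.0186 and 0.0186 with the offset, each 0.731 with an estimated correlation).

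Between the doses, 3 lipid genes were called lower at 30 nM than at 3 nM. ABCA1 was at 6.86 ± 0.506 CPM at 30 nM, a log2 difference of -2.07 from 3 nM (SE 0.23, n = 3 per group, adjusted p = 0.00843, edgeR), SCD at 161 ± 3.48 CPM, -1.55 (SE 0.14, adjusted p = 0.00257), and ANGPTL4 at 82.4 ± 9.54 CPM, -1.25 (SE 0.17, adjusted p = 0.0479). BMF (chromosome 15, 40087890 to 40108892, overlapped on the other strand by BMF-AS1) had 29.9 ± 3.01 CPM at 3 nM and 9.89 ± 2.36 CPM at 30 nM, a difference of -1.59 between the doses (SE 0.22, adjusted p = 0.0479). CXCL1 at 0.91 (SE 0.13, adjusted p = 0.0479) and ANOS1 at 1.22 (SE 0.18, adjusted p = 0.0479) were higher at 30 nM than at 3 nM.

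These 6 genes were the calls among 15553. At an unadjusted p below 0.05 there were 892, where chance gives 778, and with the offset 1569 of 14057, and groups did not overlap in 9.34% of genes, where chance gives 10%. DESeq2 called 95 genes, the offset fit 44, of which 5 were among the 6, and a fit of only these 6 libraries 0. Calls went to 2, 2 and 2 without DMSO replicate 1, 2 or 3, to 1 and 2 without 3 nM replicate 2 or 3, and to 0 and 1 without 30 nM replicate 1 or 2.

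By camera, 4 lists were lower at 30 nM than at 3 nM. The fatty acid, PPAR and LXR list had a median log2 difference of -0.30 (26 tested, adjusted p = 2.47e-13; 0.0498 with an estimated correlation, 0.731 with that and the offset; fry 0.0196), and over the list alone 7 passed, adding SREBF1 at -1.26, PLIN2 at -0.74, the pyruvate dehydrogenase kinase PDK4 at -0.83 and ACACA at -0.45 to the 3 genes above. Ribosomal protein genes had a median of -0.18 (59 tested, adjusted p = 8.35e-08; 0.653 with an estimated correlation). Immediate early genes had -0.23 (31 tested, adjusted p = 7.13e-05; 0.456 with an estimated correlation; 0.152 without 30 nM replicate 3), and DUSP5 at -0.67 passed over the list alone. MYC and ribosome biogenesis genes had -0.10 (32 tested, adjusted p = 0.0213; 0.456 with an estimated correlation), lost without 3 nM replicate 1 (0.0820), 3 nM replicate 3 (0.151) or 30 nM replicate 3 (0.138). The other 28 lists had adjusted p from 0.0504 to 0.982, and 12 lists were called without 30 nM replicate 2, 9 without 3 nM replicate 1 and 7 without DMSO replicate 1.

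Across all tested genes the log2 fold changes at 3 nM and 30 nM against DMSO had a Pearson correlation of 0.496, where simulated data with no change and the same shared control gave 0.491 (0.469 to 0.532 in 20 simulations). The Spearman correlation was 0.627 against a simulated 0.449, and 79.0% of genes had the same sign against 66.6%. The simulated libraries held no GC or length trends, so these excesses can come from such trends as well as from the doses. With the GC and length offset the Pearson and Spearman correlations were 0.365 and 0.442, and no change-free data were simulated for that fit. Part of these values may come from the 3 DMSO libraries that both comparisons use. No gene was called at both doses by edgeR, with 6 shared by DESeq2, and without 30 nM replicate 3 the shared calls were 42 higher and 28 lower, an overlap that the shared DMSO libraries can raise. With the offset no gene was called at 30 nM, so that no overlap was possible.

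Other lists fixed beforehand were not called in any comparison. Camera adjusted p at 3 nM and 30 nM against DMSO were 0.0935 and 0.724 for NCoR/SMRT and other co-repressor subunits, 0.983 and 0.954 for acetyltransferases and acetyl-lysine readers, 0.848 and 0.724 for VHL and cereblon ligase subunits, and 0.626 and 0.264 for proteasome subunits. They were 0.924 and 0.751 for cyclin-dependent kinase inhibitors and p53 targets, 0.0601 and 0.493 for MHC genes, 0.0935 and 0.493 for nuclear genes of oxidative phosphorylation, and 0.317 and 0.724 for the unfolded protein and ATF4 response. TGF-beta and YAP targets had 0.0935 and 0.329. Neuronal genes (18 of 43 tested) had 0.317 and 0.264, cancer-testis antigens (9 of 33 tested) 0.611 and 0.573, and replication-dependent histones (19 of 40 tested) 0.761 and 0.724. With the offset, the NCoR/SMRT (0.0465) and TGF-beta and YAP (0.0483) lists were called higher at 3 nM, proteasome subunits were called higher at 3 nM (0.0219) and 30 nM (4.26e-04), and so were oxidative phosphorylation genes (4.90e-04 and 0.00358). With an estimated correlation the adjusted p of these offset calls were 0.691 for NCoR/SMRT and 0.785 for TGF-beta and YAP, 0.785 and 0.766 for proteasome subunits, and 0.691 and 0.766 for oxidative phosphorylation, and without 30 nM replicate 3 the TGF-beta and YAP call was lost (0.0512). The signs of median, mean and test differed in 4, 2 and 6 lists in the 3 comparisons, none of them called.

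Markers of other cell types and mitochondrially encoded genes were not called, while ribosomal protein genes, the other sign of RNA quality, were called in each of the 3 comparisons as given above. Blood and immune markers had camera adjusted p of 0.661 and 0.493 at 3 nM and 30 nM (7 tested), fibroblast and endothelial markers 0.848 and 0.447 (7 tested), and mitochondrially encoded genes 0.394 and 0.264 (13 tested), of which MT-ND4L passed over the list alone at 30 nM (log2 0.99, 0.0414). With the offset the mitochondrial list was called higher at 30 nM (0.00358; adjusted p = 0.766 with an estimated correlation), and this was lost with the offset without 30 nM replicate 3 (0.404). Mitochondrial genes took 0.745, 0.531 and 1.12% of counts in DMSO, 1.21, 0.598 and 0.595% at 3 nM, and 0.939, 0.509 and 1.15% at 30 nM. In 3 nM replicate 1, 249 genes had at least 1 CPM and 5 times the level of any other library, against 108 in 3 nM replicate 3 and 0 to 6 in the others, and none of the 13 genes called at 3 nM was among them. Of these 249 genes, 34 were tested. Among the 249, 11 were cancer-testis antigens of the list, 5 mesenchymal, 5 neuronal and 2 fibroblast and endothelial markers (THY1 and PDGFRA). A gene with counts in only 1 library did not pass the filter, so the list tests could not show it.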

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

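The tests on the 13 genes called at 3 nM and on the transcripts of 3 nM replicate 1 were chosen after those results were seen, as was the offset for GC content and length itself.

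The response to 30 nM against DMSO differed from that to 3 nM against DMSO, by the test of 30 nM against 3 nM in edgeR, in 6 genes. The log2 differences were -2.07 for ABCA1 (adjusted p = 0.00843), -1.59 for BMF (0.0479), -1.55 for SCD (0.00257), -1.25 for ANGPTL4 (0.0479), 0.91 for CXCL1 (0.0479) and 1.22 for ANOS1 (0.0479). At 3 nM their log2 fold changes against DMSO were 2.04, 1.32, 1.58, 1.32, -1.13 and -1.49, and at 30 nM -0.04, -0.28, 0.03, 0.06, -0.23 and -0.28. The differences kept their direction in 16 alternatives, which the lack of overlap between the libraries of the doses largely set. They passed in 14 of these for SCD, 11 for ABCA1, 5 for BMF, 5 for ANGPTL4, 4 for ANOS1 and 3 for CXCL1.

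The 13 genes called at 3 nM were nearer the DMSO level at 30 nM than at 3 nM, the rises from -0.04 for ABCA1 to 1.08 for SCNN1A in log2 fold change: with falls turned to the same sign, their median log2 fold change was 1.78 at 3 nM and 0.28 at 30 nM, and the median difference between the doses was -1.25 (SD over the genes 0.45). These genes were chosen on 3 nM libraries that the difference between the doses also uses. The median was -1.37 (SD 0.51) with the GC and length offset, which argues against the GC and length trends as the whole cause. It was -1.13 (SD 0.48) without 3 nM replicate 3 and -1.42 (SD 0.48) without 3 nM replicate 1. These last 2 values cannot decide on either library as the cause, since the genes were called with all 3 libraries at 3 nM beyond those of DMSO. An exchange of labels between the whole 3 nM and 30 nM groups and a response that is weaker at the higher dose cannot be told apart, since in 13 of the 13 genes the 3 libraries of 3 nM lay beyond the 3 of 30 nM and no measurement here marks the dose. The dose itself stays open as an untested explanation.

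Leaving out 30 nM replicate 3 took the calls at 30 nM against DMSO from 0 to 2856. With the GC and length offset the same 8 libraries gave 0 calls: the median absolute log2 fold change of those genes went from 0.84 to 0.29 and its median SE from 0.21 to 0.17, so the calls ended because the changes shrank. The trends of the libraries with GC content and length are a candidate explanation for most of the size of these changes. In these 8 libraries the GC slope was negative in DMSO (-0.38, -0.10 and -0.27) and positive in 30 nM replicates 1 and 2 (0.33 and 0.30). The offset would thus also remove a response to 30 nM that followed GC content, and the explanations cannot be told apart. With the offset the lowest adjusted p was 0.064 (edgeR). An unadjusted p below 0.05 was left in 1947 genes, where chance gives 719, which leaves room for smaller effects of the dose. With all 9 libraries the offset left 886 of 14057 genes at that level and a lowest adjusted p of 0.775. Whether 30 nM replicate 3 is a DMSO library under a wrong label cannot be told apart from a weak response. After the offset it stood at 0.178 on the axis from DMSO (0) to the other 30 nM libraries (1). Held-out DMSO libraries reached 0.337 and the other 30 nM libraries began at 0.333. The axis was drawn again without each held-out library, so these positions are not on a common axis. For 30 nM replicates 1 and 2 it ended at a single library, whose noise can lower their positions. Without the offset, on axes drawn in the same way, 30 nM replicate 3 stood at 0.134. This was within the DMSO libraries (-0.0431 to 0.359) and below the other 30 nM libraries (0.519 and 0.572). The chi-square per degree of freedom of 30 nM replicate 3 was 14.4 with DMSO replicate 3 against 121 and 159 with its own group. But these values carry the GC trends of the libraries as well.

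Library 3 nM replicate 1 held transcripts that the other 8 libraries lacked, such as UCHL1 (4234 counts), MAGEA4 (2398), CDKN2A (1554), THY1 (683), FOXD1 (534), PRAME (496), MTAP (328) and CDKN2B (255), each at 0 elsewhere. MDA-MB-231 is known to have lost the CDKN2A region of chromosome 9 on both copies, and genes within 500000 bases of CDKN2A had 2206 counts in this library against at most 1 in any other, which is consistent with RNA of other human cells in this library. A response of the cells to 3 nM is argued against: 0 of 115 genes at 0 counts in all DMSO and 30 nM libraries and at 1 CPM or more in this library reached 1 CPM in another 3 nM library. Greater sequencing depth is argued against too, since with each library thinned to the lowest total 257 genes stood at least 5 times above any other library, against 94 for the next highest, 3 nM replicate 3. Of the 13 genes called at 3 nM, 0 are among these transcripts, though a gene high in 1 of 3 libraries would rarely be called. The level of the 13 genes in this library was 0.568 to 1.23 times the mean of the other 3 nM libraries.

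The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. At 3 nM against DMSO the real split gave 13 calls by edgeR and the highest of the others 0, so that 1 split reached the real count. At 30 nM against DMSO the real split gave 0 and the highest of the others 0, so that 10 splits did. At 30 nM against 3 nM the real split gave 6 calls and 2 splits reached that, the other with 1653 calls: it set 3 nM replicates 1 and 2 with 30 nM replicate 3 against 3 nM replicate 3 with 30 nM replicates 1 and 2. This points to a structure of the samples other than the dose, and with the GC and length offset that split gave 1 call and the real split 44.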

How the results depend on the processing

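The offset for GC content and length, the fits that leave out 2 libraries or combine the offset with a library left out, and voom with sample weights were chosen after seeing the data. The 13 genes named at 3 nM kept their direction in each of 16 settings, which the lack of overlap between their groups largely set. HDAC3 kept its direction at both doses as well. With each library left out it ran from 0.20 to 0.44 at 3 nM and 0.16 to 0.25 at 30 nM. What changed is given below; unless a setting fits fewer genes or libraries or a stricter threshold, the cause was not tested. The lowest total was that of 3 nM replicate 3, with 16557756 counts, and thinning the other libraries to it did not give them as many zero counts (at most 26 against 149 of 1009 genes), so depth alone does not set its precision. No pairing of the libraries by replicate number was seen. Correlations of same-number deviations ran from -0.219 to 0.198, and 2 of 9 were above 0.1. Of the libraries, 0 correlated best with their own number in both other groups. These deviations also carry the GC trends and the outlying libraries, which could hide a pairing, so it is not excluded.

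Calls at 3 nM against DMSO (13) were 227 with no filter, 354 with DESeq2, 2 with a replicate block, 5 at an adjusted p of 0.01, 64 with the offset (14057 genes tested), 40 with the offset without 30 nM replicate 3, 881 with the offset without 3 nM replicate 1, 72 without both replicates numbered 3 of the doses and 4777 with voom weights, and ran from 0 to 127 with each library left out. Calls at 30 nM against DMSO (0) were 2, 14, 4938 and 7177 with no filter, DESeq2, both replicates 3 left out and voom weights, and ran from 0 to 2856. Weights of voom ran from 0.225 for 30 nM replicate 3 to 4.29 for DMSO replicate 3. Calls at 30 nM against 3 nM (6) were 2 with RLE (both lower), 40 with no filter, 95 with DESeq2, 0 with only the 6 libraries, 1 with the block, 2 at 0.01, 44 with the offset, 11 and 156 with the offset without 30 nM replicate 3 or 3 nM replicate 1, 19 without both replicates 3 and 49 with voom weights, and ran from 0 to 4.

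Lists called at 3 nM (10) were 17 with no filter and 0 with an estimated correlation, and ran from 8 to 12 with each library left out. At 30 nM (4) they were 0 with an estimated correlation and ran from 3 to 4. At 30 nM against 3 nM (4) they were 7 with RLE, 9 with no filter, 1 with an estimated correlation, 8 with the offset, 7 and 15 with the offset without 30 nM replicate 3 or 3 nM replicate 1, and ran from 4 to 12. The correlation between doses (0.496) was 0.396 with no filter, 0.679 with the stricter filter, 0.320 with DESeq2 and 0.365 with the offset, and ran from 0.299 to 0.554. Calls shared by the doses (0) were 1 with no filter, 6 with DESeq2 and 36 without both replicates 3, and ran from 0 to 70.

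Signs turned with the offset for HDAC8 (0.26 at 3 nM, 0.29 at 30 nM), HDAC2 (0.11 and 0.054), HDAC9 at 30 nM (0.16) and HDAC10 at 3 nM (-0.14). With each library left out HDAC8 ran from -0.23 to -0.08 at 3 nM and from -0.17 to -0.0021 at 30 nM, HDAC10 from -0.25 to 0.36 and from -0.64 to 0.29, and HDAC11 at 3 nM from -0.29 to 0.035.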

Other observations

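Genes in the first paragraph were chosen after their values were seen, from the fit with the GC and length offset, itself chosen after seeing the data.

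With the offset, 46 genes rose and 18 fell at 3 nM against DMSO (edgeR, n = 3 per group). TBL1XR1, a subunit of the NCoR/SMRT complexes that hold HDAC3, rose by a log2 fold change of 1.19 (SE 0.16, adjusted p = 0.00885), where the fit without the offset gave 0.43 (adjusted p = 0.320). Rises also included the class IIa deacetylase HDAC5 (0.96, adjusted p = 0.0259), the lipid genes FASN (0.92, 0.0457) and PLIN2 (1.04, 0.0441), the TGF-beta signal transducer SMAD3 (0.74, 0.0197), the S100 calcium-binding genes S100A3 (1.25, 0.0165) and S100A4 (0.81, 0.0457), the heme oxygenase gene HMOX1 (1.29, 0.0354) and DDIT4 (1.17, 0.0354). Genes of invasion and matrix turnover among them were PLAU (0.74, 0.0393) and ITGA5 (0.69, 0.0457). Falls included the histone acetyltransferase KAT2B (-1.17, 0.0326), the BMP modulator BMPER (-1.29, 0.0209), the activin-binding protein FSTL3 (-0.93, 0.0209) and the cell cycle inhibitor CDKN1A (-0.72, 0.0417). Of the 64 genes, 62 were also called with the offset and without 3 nM replicate 1, where 881 genes were called in all. The other 2 were SERPINB2 (3.99, adjusted p = 0.0381; 2.82 and 0.0714 without that library) and RAB3B (4.56, 0.0441; 2.38 and 0.0942). TBL1XR1, DDIT4, PLAU, SMAD3, ITGA5, CDKN1A and HDAC5 overlap genes on the other strand, and S100A3 and S100A4 overlap each other.

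Library 3 nM replicate 3 had the lowest total, 16557756 counts. Of 1009 genes at 1 to 2 CPM it held 0 counts for 149, against at most 26 in the other libraries thinned to the same total.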
